A study of Rattus norvegicus with 2 samples.

How the data were processed

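RNA from hippocampal synaptosomes, a biochemical fraction of pinched-off nerve endings with their attached postsynaptic membranes, and RNA from the total hippocampus of Sprague Dawley rats at postnatal day 70 were each measured on 1 Affymetrix rat expression array, as the AFFX names of its control probe sets show. Per the labels' protocols, total RNA was purified on columns, cDNA was made with the SMART amplification kit and an oligo(dT) primer carrying a T7 promoter, and biotin-labelled cRNA was transcribed from it. The labels do not say how many animals went into either sample. The number of arrays, 1 per group, limits the precision, and no test between the groups was possible.

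The authors' deposited table holds linear intensity values for 8799 probe sets, of which 59 are control probe sets. The scanner software and its background correction are not given in the sources used here. The deposited intensities are whole numbers, and 25.2% of the non-control values on the synaptosome array and 31.4% on the hippocampus array were at or below 0, as a difference between matched and mismatched probes can give. The mean after removal of the lowest and highest 2% of probe sets was 2500 on both arrays, so the authors' intensities were taken as already scaled to one target and no further scaling was applied. The median negative value had a size of 513.5 on the synaptosome array and 930.5 on the hippocampus array.

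Every choice below was fixed before the data were examined unless stated otherwise. A floor at percentile 25 of the pooled non-control values had been chosen, with percentiles 10 and 50 as alternatives. Among the choices fixed beforehand, percentiles 10 and 25 turned out to be -1086 and -133, which have no logarithm, so percentile 50, a signal of 846, was used as the floor. Values under the floor were set to it and log2 was taken. The log2 ratio is synaptosome minus total hippocampus, and its median over probe sets past the filter, -0.17, was subtracted. Probe sets whose mean log2 level lay at or above the median of all non-control probe sets, 10.07 or a signal of 1078, passed the filter, and 4370 did. A ratio with 1 array at the floor is, with both signals taken at face value, a lower bound on the centred fold and is written "at least". The 95th percentile of the size of negative values was 2912.6 on the synaptosome array and 5280.25 on the hippocampus array, above the floor. A bound that rests on signals within this spread is not a guaranteed minimum. All folds include the centring, which makes those of higher genes 1.13 times the quotient of the signals and those of lower genes smaller by the same factor, so a bound can exceed the quotient of the printed signals and holds only with this centring. A probe set at the floor on both arrays has no ratio. Several named genes had such probe sets beside the one used, and these are not always mentioned.

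Gene names came from the platform's annotation. Of the 8740 non-control probe sets, 7006 had 1 gene symbol, 308 had several and 1426 are unnamed here. The next counts cover all probe sets with 1 gene symbol in the platform's annotation, not only the non-control ones. For 6994 of them the gene identifier was found in the rat RefSeq gene table of assembly GRCr8, which changed 0 symbols. The platform's symbol was kept for 24. A gene with several probe sets past the filter took the one with the highest mean level. This left 2735 genes, of which 2175 lay above the floor on both arrays, 241 on the synaptosome array only and 319 on the hippocampus array only.

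Counts of genes at least 2-fold higher or lower were made without a p-value. For 27 gene lists, the median log2 ratio of the filtered members was placed among the medians of 10000 random lists of the same size, drawn from the filtered genes and matched on deciles of mean level. A percentile under 2.5 or above 97.5 was called outside the random lists; 1.35 of 27 lists would be so by chance. These percentiles describe these 2 arrays, since genes are not replicates. Intervals of list medians are 95% bootstrap intervals over members. The only error that could be measured was the standard deviation (SD) of the log2 ratio between probe sets of one gene, which leaves out animals, preparations and amplifications. The genes named are the 15 with the highest and the 15 with the lowest ratio, the Kv1 list in full, and from each list up to 4 members farthest in the direction of its median and the member farthest the other way. A gene outside this rule is marked as chosen after its values were seen.

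The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. They were tested on simulated data for this comparison. With no noise, 96.9% of genes changed by 3 on the log2 scale and 92% of those changed by 1.5 were recovered at the 2-fold threshold among 2741 genes, and 0% of unchanged genes passed it. With noise of the SD between probe sets of one gene, these shares were 96.9%, 63.3% and 25.2% among 2743 genes. Of 100 random lists of 30 genes, 3% fell outside without a shift, 52% after a shift of 0.5 and 100% after a shift of 1.

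Alternatives were no centring, quantile normalization, a loess correction of the ratio on the mean level, no filter, a filter at percentile 75 of the mean level, the mean over a gene's probe sets, and leaving out probe sets whose names mark them as shared or shortened designs (_s, _x, _f, _r, _i, _g). A floor at percentile 75, 2798.5, a restriction to genes above the floor on both arrays, and a measure of repeatability with one probe set per source sequence were added after the data were seen. Control probe sets entered no gene count.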

Results

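The comparison asked which mRNAs are more abundant in hippocampal synaptosomes than in the hippocampus as a whole, with the mRNA of the voltage-gated potassium channel Kv1.1, encoded by Kcna1, named in the title of the study. There was 1 array of synaptosomal RNA and 1 of total hippocampal RNA, so each value below is a single measurement. The arrays ranked the 8740 non-control probe sets with a Spearman correlation of 0.78 across probe sets. On the synaptosome array 4295 probe sets lay above the floor of 846, and on the hippocampus array 4443 did. The brightest signal was 96504 on the synaptosome array and 519581 on the hippocampus array.

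Kcna1 had a higher signal in synaptosomes with both of its probe sets. The brighter probe set (X12589cds_s_at) read 16896 in synaptosomes and 3889 in the total hippocampus, a log2 ratio of 2.29 or 4.89-fold. The other (M26161_at) read 8853 in synaptosomes and 785, under the floor, in the hippocampus, which is at least 11.8-fold with the centring that all folds here include and at least 10.5-fold against the floor without it. Both hippocampus readings lay under the 95th percentile of the size of negative values on that array, 5280.25. The sizes of both folds are therefore uncertain, and the bound is not a guaranteed minimum. Among the 2175 genes above the floor on both arrays, Kcna1 ranked 21 from the top, and among all 2735 filtered genes it ranked 60. Of the 9 genes of the Kv1 list on the array, which holds Kv1 pore-forming subunits and their partners, 4 passed the filter. Kcnab2, the auxiliary β2 subunit, was 2.46-fold higher with its brighter probe set and at least 2.59-fold lower with the other. Kcna5 was at least 2.02-fold higher with a synaptosome signal of 1521, close to the floor, and a hippocampus reading of -7771, so its bound is uncertain. Kcna4 had a log2 ratio of 0.53. The probe sets of Kcna2, Kcna3, Kcna6, Kcnab1 and Kcnab3 were at the floor on both arrays, so that neither presence nor a difference was detectable for them. The median of the 4 filtered members was 1.16, at percentile 97.2 of random lists of the same size (over the 6 alternatives that left enough members, medians of 0.77 to 1.16, percentiles 89.9 to 98.97). With the mean over probe sets the median was 0.77 at percentile 89.9, while without the filter and without suffixed probe sets the percentile was 98.97 and 97.8, outside the middle 95% of random lists. For each list below, the ranges of its median and percentile over the alternatives are given in the same way.

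**Figure D1:**
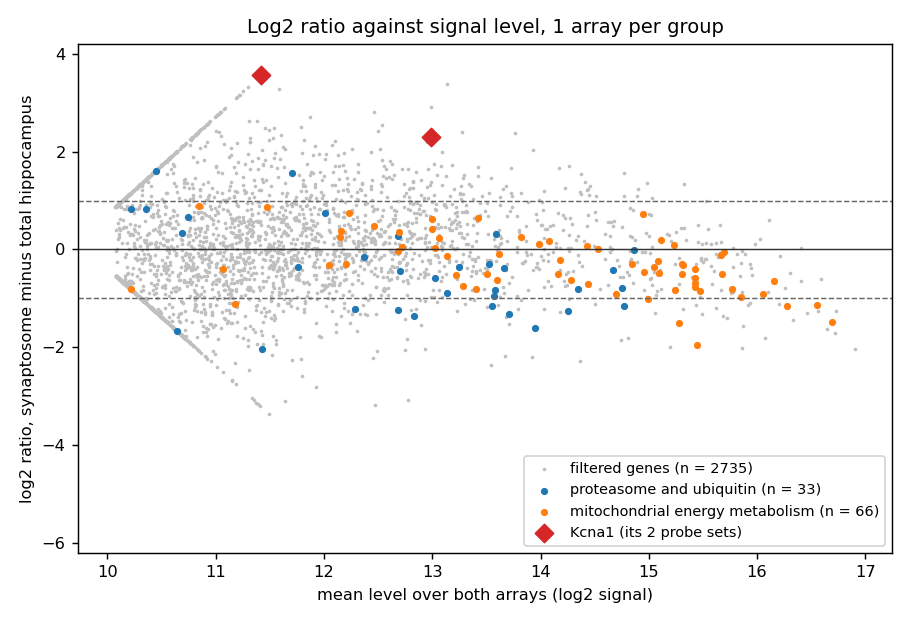
Log2 ratio of synaptosome over total hippocampus (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis) for the 2735 filtered genes, each a grey point, with the proteasome and mitochondrial lists in colour, both Kcna1 probe sets as diamonds and dashed lines at 2-fold; the diagonal edges on the left are genes at the floor on 1 array. Kcna1 lies at 2.29 and 3.56, the latter a lower bound on the centred ratio, and the median of the brightest of 10 equal groups of probe sets above the floor on both arrays lies at -0.36.

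Across the 2735 filtered genes, 522 were at least 2-fold higher and 391 at least 2-fold lower in synaptosomes, and 1822 lay between. These were 19.1% and 14.3% of the genes. In the simulation with noise between probe sets, 25.2% of unchanged genes passed 2-fold in either direction, so noise of that size could give many of these calls. Without centring the counts were 403 higher and 532 lower, so the share of higher genes among those past 2-fold was 57.2% with centring and 43.1% without. Slc12a5, the neuronal potassium-chloride cotransporter KCC2, was 10.5-fold higher, with signals of 27432 and 2946. Cdh22, a cadherin, was 7.49-fold higher and Ptprn, a membrane protein of dense-core vesicles, 7.06-fold higher. Supt5h, a transcription elongation factor, was 9.76-fold higher with 1 probe set and had a log2 ratio of -0.08 with another. The second probe set of Cdh22 was at least 1.77-fold lower. The other 11 of the 15 highest genes were at the floor in the hippocampus. They included Pttg1, or securin, at least 12.3-fold higher, and Pdyn, the precursor of the dynorphin opioid peptides, at least 11.6-fold higher with 1 probe set and at least 2.21-fold lower with another. Gaa, a lysosomal glucosidase, was at least 9.93-fold higher and Ppp1cc, a catalytic subunit of protein phosphatase 1, at least 9.41-fold higher. Nos1ap, an adaptor of neuronal nitric oxide synthase, was at least 8.96-fold higher, and Inpp4a, a phosphoinositide phosphatase, at least 8.93-fold higher. The remaining bounds were 8.69-fold for Smo, 8.54-fold for Anapc5, 7.39-fold for Nras, 7.34-fold for Iqsec1 and 7.02-fold for Ptgir. The other probe set of Nras was at the floor on both arrays. In the hippocampus Pttg1 read -4671, the higher probe set of Pdyn -13765 and Ptgir -7632. The sizes for Pdyn and Ptgir exceeded the 95th percentile of negative values on that array, 5280.25, so their bounds are less certain. The hippocampus signals of Slc12a5, Cdh22, Ptprn and Supt5h, 2946, 3151, 2250 and 1041, lay under that size, so their folds are uncertain too.

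Among the 15 lowest genes, 5 were above the floor on both arrays. Kitlg, the ligand of the receptor Kit, was 9.03-fold lower in synaptosomes. Ifitm3, an interferon-induced membrane protein, was 8.55-fold lower, and Lta4h, which makes leukotriene B4, was 8.45-fold lower. Kcnk1, a background potassium channel, was 6.97-fold lower, with signals of 1386 and 10870. Ephx2, the soluble epoxide hydrolase, was 5.98-fold lower with 1 probe set and at least 4.43-fold lower with another. The other 10 were at the floor in synaptosomes. Gadd45a, a growth arrest gene, was at least 9.23-fold and at least 4.11-fold lower with 2 probe sets and had a log2 ratio of -0.27 with another. Car4, a membrane-bound carbonic anhydrase, was at least 5.69-fold and at least 3.59-fold lower with its 2 probe sets. The bounds were 10.3-fold for Ghr, 8.95-fold for Foxd3, 8.75-fold for Pyy, 8.46-fold for Ppp1r13l, 8.25-fold for Rab33b, 6.72-fold for Defb1, 6.42-fold for Adam3a and 6.40-fold for Cyp4a3. The other probe sets of Ghr, Foxd3, Pyy, Defb1 and Lta4h were at the floor on both arrays. Those of Kitlg and Rab33b did not pass the filter. They read 1341 and 1253 in the hippocampus and were under the floor in synaptosomes, with bounds of -0.49 and -0.40 on the log2 scale. The Pyy probe set used read -6018 in synaptosomes, a size beyond the 95th percentile of negative values there, 2912.6, so its bound is less certain. The synaptosome signals of Kitlg, Ifitm3, Lta4h, Kcnk1 and Ephx2, 1779, 1030, 2281, 1386 and 1375, lay under that size. Their folds are uncertain too.

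Probe sets of one gene differed nearly as much as probe sets of different genes. Over 658 genes with several filtered probe sets, the SD of the log2 ratio within a gene was 0.90, against 1.06 over all filtered probe sets with 1 gene symbol. All probe sets had one sign in 59.0% of these genes, against 44.1% after probe sets were shuffled over genes. In 46 genes every probe set was at least 2-fold higher and in 19 every one at least 2-fold lower, where 1000 shuffles gave means of 21.1 and 9.01 and maxima of 34 and 19. Many of these pairs are designs on one source sequence; with one probe set per source sequence, a comparison added after the results were seen, over 429 genes, the counts were 26 and 12 against shuffle maxima of 24 and 12, and 55.9% of genes had one sign against a maximum of 55.5%. In 36 genes 1 probe set was at least 2-fold higher and another at least 2-fold lower. The Kcna1 ratio of 2.29 was larger than this SD; a 2-fold difference, 1 on the log2 scale, was close to it.

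**Figure D2:**
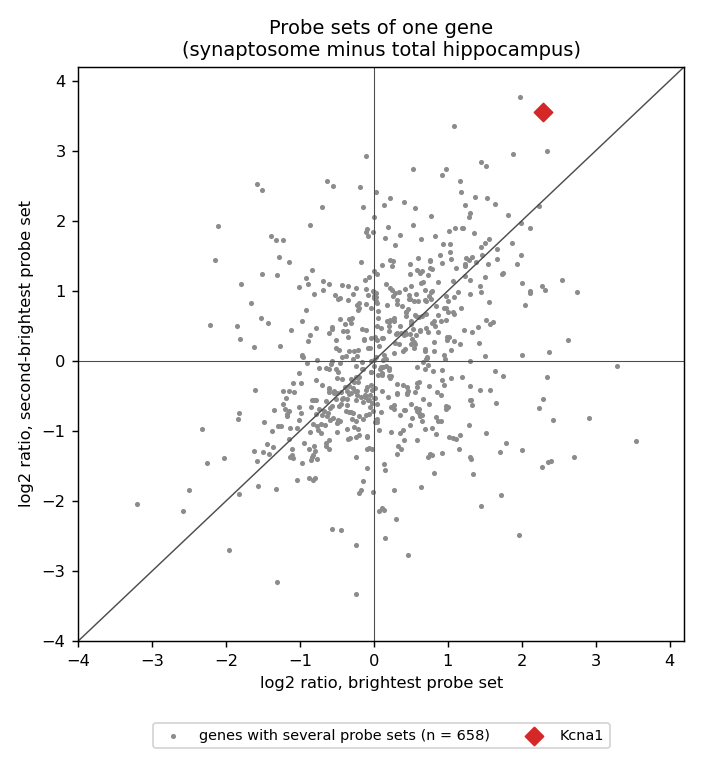
Log2 ratios of synaptosome over total hippocampus for the brightest (horizontal axis) and second-brightest (vertical axis) filtered probe set of each of 658 genes, with the line of equality; Kcna1 is the diamond. The points scatter widely around the line, with a Pearson correlation of 0.29 across genes, which are not independent replicates.

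Potassium channels other than Kv1 were higher in the median and divided in their extremes. Of 16 filtered members, 7 were at least 2-fold higher, 3 at least 2-fold lower and 6 lay between, with a median log2 ratio of 0.85 (95% interval -0.56 to 1.11) at percentile 98.6 (alternatives -0.12 to 1.11, percentiles 8.8 to 98.9). Kcnh1 was at least 3.62-fold higher, Kcnj11 at least 2.89-fold and Kcnma1, the calcium-activated BK channel, at least 2.16-fold. The other probe sets of Kcnma1 were at the floor on both arrays. Kcnmb1, a BK channel subunit, was 3.90-fold higher with 1 probe set and 5.61-fold lower with another. Kcnk1 lay farthest the other way. The mean was 0.31, and with the higher floor of 2798.5 the median of the 7 members left was -0.12. The call also ended without the filter at a median of 0.27 and percentile 78.2 and with the mean over probe sets at 0.33 and 83.0. It ended as well, with a median of 0.78 in both, with the filter at percentile 75 of the mean level over 5 members and with genes above the floor on both arrays over 9, at percentiles 90.6 and 97.4.

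Neuropeptides and secretory granule proteins had a median of 0.67 (-0.26 to 1.05) at percentile 98.96 (alternatives 0.00 to 0.83, percentiles 44.8 to 99.5), with 5 of 16 members at least 2-fold higher and 2 at least 2-fold lower. Pcsk2, a prohormone convertase, was 2.73-fold higher, Pam, which amidates peptides, 2.47-fold with its brightest probe set and at least 2.27-fold lower with 1 of its others, and Scg3, a granin, 2.19-fold. Npy was 2.62-fold lower. Without the filter the median was 0.00, at percentile 44.8. The call also ended without suffixed probe sets and with genes above the floor on both arrays, at percentiles 93.3 and 95.3, with a median of 0.52 in both.

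mRNAs with known dendritic localization had a median of 0.37 (-0.00 to 0.94) at percentile 94.7 (alternatives 0.17 to 0.62, percentiles 88.4 to 99.8), inside the range of random lists. Of 30 members, 8 were at least 2-fold higher, 2 at least 2-fold lower and 20 lay between. Besides Kcna1, the highest were Ntrk2, the receptor of BDNF, at 4.57-fold, Arc, an activity-regulated synaptic gene, at 3.59-fold, and Itpr1, an intracellular calcium channel, at 3.36-fold with 1 probe set and a log2 ratio of -0.21 with another. The other probe set of Ntrk2 was at the floor on both arrays. Snap25 was the lowest, at 2.96-fold lower. The percentile was 99.2 after quantile normalization, 99.8 after loess correction and 98.2 with the mean over probe sets, and 88.4 without suffixed probe sets. The median was 0.20 without centring and 0.17 with the floor of 2798.5.

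Lists of synaptic proteins had medians near 0, which without centring were -0.09 for postsynaptic and -0.10 for presynaptic genes. Postsynaptic density and spine proteins had a median of 0.08 at percentile 66.5 (alternatives -0.16 to 0.25, percentiles 26.1 to 85.8), with 4 of 22 at least 2-fold higher and 3 at least 2-fold lower. Dlgap4 was at least 3.99-fold higher with 1 probe set and at least 2.43-fold lower with another. Synpo, an actin-associated spine protein, was at least 3.26-fold higher, Shank1, a scaffold, at least 2.95-fold and Dlgap1 at least 2.28-fold. Nsf was 3.10-fold lower. Presynaptic genes had a median of 0.07 at percentile 67.8 (alternatives -0.10 to 0.35, percentiles 50.6 to 92.0), with 8 of 38 at least 2-fold higher and 5 at least 2-fold lower. The complexins Cplx2 and Cplx1 were 2.61-fold and at least 2.53-fold higher and Synj1, a vesicle-recycling phosphatase, 2.60-fold. Stx1a had log2 ratios of 1.32 with 1 probe set and -0.63 with another. Rab3c was 3.83-fold lower. With the filter at percentile 75 of the mean level the presynaptic median was 0.35.

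Receptor and other channel lists also lay inside the random range, and without centring the medians of glutamate receptors and of sodium and calcium channels were -0.05 and -0.07. With the filter at percentile 75 of the mean level they were 0.59 and 0.56; glutamate receptors had a median of 0.62 with the mean over probe sets, and sodium and calcium channels one of 0.72 with genes above the floor on both arrays. GABA and glycine receptors had a median of 0.53 at percentile 91.0 (alternatives 0.07 to 0.83, percentiles 55.7 to 97.1), with 5 of 13 at least 2-fold higher and 0 lower. Gabbr2 was 3.25-fold higher with 1 probe set and at least 2.47-fold lower with another. Gabra3, Gabra6 and Gabrd were at least 2.76-fold, 2.70-fold and 2.69-fold higher. Gabra2 lay farthest the other way at -0.63. Glutamate receptors had a median of 0.12 at percentile 59.0 (alternatives -0.05 to 0.62, percentiles 51.7 to 95.3), with 2 of 17 at least 2-fold higher and 15 between. Grin3a was at least 4.30-fold and Grin2d at least 2.07-fold higher, while Gria3 had log2 ratios of 0.92 and -0.27 with 2 probe sets, Grm3 one of 0.76 and Grik4 one of -0.90. Sodium and calcium channels had a median of 0.10 at percentile 59.9 (alternatives -0.07 to 0.72, percentiles 55.4 to 97.2), with 6 of 16 at least 2-fold higher and 2 lower. Scn7a was 3.36-fold, Cacna1c 2.59-fold, Scn2a 2.48-fold and Cacna2d1 2.40-fold higher, and Cacna1g, a T-type channel, at least 4.60-fold lower. The other probe sets of Scn7a and Cacna1c were at the floor on both arrays.

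Genes of mTOR signalling, a regulator of translation named in the study's title, had a median of 0.44 at percentile 92.9 (alternatives -0.01 to 0.44, percentiles 40.9 to 92.9), with 4 of 15 at least 2-fold higher and 1 lower. The kinase Akt1 was 5.81-fold higher with 1 probe set and at least 2.22-fold with another. Tsc2 was 3.61-fold and Mtor itself 3.25-fold higher, each on 1 probe set. Irs2 was at least 5.36-fold higher with 1 probe set and had negative log2 ratios with 2 others. Rictor was 2.48-fold lower. The median was 0.06 at percentile 56.0 with the mean over probe sets and -0.01 at percentile 40.9 without the filter. Immediate early genes had a median of 0.27 at percentile 80.1 (alternatives 0.10 to 0.87, percentiles 73.0 to 98.98), with 4 of 17 at least 2-fold higher and 3 lower. Nptx2 was 3.68-fold higher, Fos 2.28-fold and Dusp6 2.17-fold, and Atf3 was at least 3.03-fold lower. Another probe set of Fos had a log2 ratio of -0.23. With the filter at percentile 75 of the mean level the median was 0.87 at percentile 98.98. Cytoskeletal and motor genes had a median of 0.38 at percentile 95.5 (alternatives 0.21 to 0.54, percentiles 83.2 to 99.35), with 8 of 27 at least 2-fold higher and 3 lower. Map1a was 3.66-fold, the dynein chains Dync1i1 and Dync1h1 3.34-fold and 2.53-fold, and Sptan1, a spectrin, 2.52-fold higher, while Tmsb4x was 3.26-fold lower. The percentile was 98.9 with the floor of 2798.5, 99.1 with loess correction, 99.35 without the filter and 99.35 after quantile normalization, and 83.2 at a median of 0.25 without suffixed probe sets. Without centring the median was 0.21. Nuclear and chromatin genes had a median of 0.27 at percentile 86.0 (alternatives 0.10 to 0.27, percentiles 69.1 to 90.3), with 5 of 28 at least 2-fold higher and 2 lower. The transcription factor Mef2d was 5.26-fold higher, Thra 2.36-fold, and Lmna and Hes1 at least 2.97-fold and 2.23-fold, and Rara had a log2 ratio of -1.32.

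Proteasome and ubiquitin genes were lower in synaptosomes. Their median was -0.44 (-0.88 to -0.29), at percentile 0.56 of random lists (alternatives -0.79 to -0.42, percentiles 0 to 0.56), and it lay under percentile 2.5 in all 9 alternatives that could be run. Leaving out the centring, 1 of the 9, shifts the list and the random lists alike and cannot change the percentile. Of 33 members, 10 were at least 2-fold lower, 2 at least 2-fold higher and 21 between. The ubiquitin ligase Ube3a was 4.08-fold lower, the immunoproteasome subunit Psmb8 at least 3.20-fold, the core subunit Psmb4 3.04-fold and the ATPase subunit Psmc2 2.58-fold. Other probe sets of Psmb4 were 1.98-fold and 1.33-fold lower. Ube2g2 was at least 3.06-fold higher.

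Nuclear-encoded genes of mitochondrial energy metabolism had a lower median in synaptosomes, with 45 of 66 members below 0 and 21 above. The mitochondrial median was -0.34 (-0.50 to -0.12), at percentile 0.78 (alternatives -0.51 to -0.18, percentiles 0.11 to 5.36). Its difference from the proteasome median was not tested. Of 66 members, 7 were at least 2-fold lower, 0 at least 2-fold higher and 59 between. Ndufab1 of complex I was 3.88-fold lower, Atp5if1, the inhibitor of ATP synthase, 2.83-fold, Uqcr11 of complex III 2.80-fold and Ndufa4 2.22-fold. The other probe set of Uqcr11 was 1.82-fold lower. Atp5f1d lay farthest the other way at 0.90. The call ended with loess correction, at a median of -0.18 and percentile 3.73, and with quantile normalization, at -0.20 and 2.70. It also ended, with medians about as low, with the floor of 2798.5, at -0.40 and 2.69, and with the filter at percentile 75 of the mean level, at -0.31 and 5.36.

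Ribosomal protein genes had a median of 0.10 at percentile 93.8 (alternatives -0.07 to 0.19, percentiles 82.9 to 95.5), a mean of -0.03 and a median of -0.07 without centring, with 1 of 39 at least 2-fold higher, 4 lower and 34 between. The 1 higher, Rpl19l4, a copy of Rpl19, was 3.26-fold higher on a probe set that other copies of Rpl19 may also bind, so its identity is uncertain. Rpsa, Rpl22 and Rpl13a had log2 ratios of 0.86, 0.84 and 0.77. Rps15 was 3.51-fold lower with its brightest probe set and had log2 ratios of -0.29 and 0.31 with 2 others. Translation factors and RNA-binding proteins had a median of -0.06 at percentile 38.9 (alternatives -0.23 to 0.08, percentiles 28.5 to 62.0), with 1 of 24 at least 2-fold higher and 2 lower. Eif2s1 was 2.93-fold and Eif2b4 at least 2.21-fold lower, Eif4e and Eif4a2 had log2 ratios of -0.83 and -0.75, and Eif2b2 was 2.27-fold higher. Glycolysis genes had a median of 0.02 at percentile 68.1 (alternatives -0.16 to 0.37, percentiles 41.8 to 89.6), a mean of -0.05 and medians of -0.15 without centring, 0.34 after loess correction and 0.37 after quantile normalization. Of 14 members, 1 was at least 2-fold higher and 2 lower. Hk1 was 2.88-fold higher and Aldoa 3.96-fold lower, and Pfkl, named after its value was seen, 3.05-fold lower. Slc2a3, Slc2a1 and Pfkm had log2 ratios of 0.94, 0.88 and 0.74. Chaperones had a median of 0.09 at percentile 54.1 (alternatives -0.08 to 0.20, percentiles 38.2 to 80.9), or -0.08 without centring, with 3 of 23 at least 2-fold higher and 1 lower. Canx was 2.93-fold higher, though 1 of its 4 filtered probe sets had a log2 ratio of -0.35, Hmox1 and Hspa1a at least 2.97-fold and 2.71-fold higher, and Stip1 2.28-fold lower.

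Markers of cell types differed by list. Endothelial, mural and meningeal markers had the lowest median of the lists with more than 5 members, -0.54 (-1.08 to -0.09) at percentile 4.35 (alternatives -0.71 to -0.11, percentiles 1.65 to 33.2), with 7 of 21 at least 2-fold lower and 1 higher. Kdr, a VEGF receptor, was at least 4.09-fold lower, Slco1a4, a transporter of the blood-brain barrier, at least 3.73-fold and Vtn at least 2.65-fold. Sparc was 3.08-fold lower with its brightest probe set, while 2 others had log2 ratios of 0.20 and 0.86. Igfbp2 was at least 3.33-fold higher. With loess correction, quantile normalization and no filter the percentile was 1.65, 1.76 and 2.05, but 8 of the 21 members were at the floor on 1 array, and the median was -0.13 at percentile 22.7 with genes above the floor on both arrays, -0.11 at percentile 33.2 with the filter at percentile 75 of the mean level and -0.22 at percentile 24.5 with the floor of 2798.5. Red blood cell transcripts had a median of -0.81 over 5 members at percentile 6.66 (alternatives -1.28 to -0.81, percentiles 0.02 to 6.72), or -1.28 at percentile 0.02 over 4 members with the floor of 2798.5. Hbb-b1 and Hbb were 5.17-fold and 4.58-fold lower, but these near-identical globin genes share sequence and cannot be told apart with certainty, and Hba-a3 had a log2 ratio of -0.81. Slc4a1 had a log2 ratio of -0.15 with its brightest probe set, was 4.57-fold higher with another and had a log2 ratio of -0.91 with the remaining one.

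Oligodendrocyte and myelin markers had a median of -0.13 at percentile 16.4 (alternatives -0.62 to 0.25, percentiles 0.67 to 74.3), with 4 of 16 at least 2-fold lower and 2 higher. Mbp was 4.70-fold, Mobp 3.55-fold, Apod 3.51-fold and Mog 2.49-fold lower, while Pdgfra, a marker of oligodendrocyte precursors, was at least 5.95-fold higher. The bound for Pdgfra rests on 1 probe set, as its others were at the floor on both arrays. The median was -0.62 at percentile 1.83 without suffixed probe sets, -0.52 at percentile 0.67 with the filter at percentile 75 of the mean level and 0.25 at percentile 74.3 without the filter. Astrocyte markers had a median of 0.18 at percentile 87.7 (alternatives 0.01 to 0.35, percentiles 69.2 to 97.0), with 6 of 25 at least 2-fold higher and 3 lower. Acsl6 was 3.38-fold, S100b 2.53-fold and Ptprz1 2.27-fold higher, and Sparc lay farthest the other way. The astrocyte median was 0.01 without centring and 0.05 without the filter. Microglia and immune markers had a median of -0.03 at percentile 43.6 (alternatives -0.49 to 0.36, percentiles 9.26 to 79.2), with 2 of 16 at least 2-fold higher and 2 lower. Cd37 was at least 3.34-fold and RT1-Bb 2.24-fold lower, Il1b and Ptprc had bounds of -0.80 and -0.68, and RT1-Ba, which shares sequence with other histocompatibility genes, was 2.85-fold higher with 1 probe set and at least 2.04-fold lower with another. Choroid plexus and ependymal markers had a median of 0.25 over 8 members at percentile 67.7 (alternatives -0.09 to 0.66, percentiles 37.0 to 91.0), with Igfbp2 and Kl, at least 2.38-fold, on the higher side, Ace at 0.81, Igf2 at 0.49 and Aqp1 at least 2.06-fold lower.

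Markers of excitatory hippocampal neurons had a median of -0.05 at percentile 48.9 (alternatives -0.22 to 0.41, percentiles 39.0 to 93.4), a mean of 0.38 and medians of 0.38 after quantile normalization and 0.41 after loess correction, with 5 of 17 at least 2-fold higher and 2 lower. Snap25 was lower with all 4 of its probe sets, by log2 ratios from -0.74 to -1.79, and Nrgn was 2.01-fold lower with 1 probe set and had a log2 ratio of -0.17 with the other. Hpca and Calb1 had log2 ratios of -0.86 and -0.82, and Cnih2, an AMPA receptor partner, was 4.37-fold higher. Inhibitory neuron markers had a median of 0.00 at percentile 42.8 (alternatives -1.03 to -0.06, percentiles 0.88 to 42.8), a mean of -0.12 and a median of -0.17 without centring, with 2 of 12 at least 2-fold higher and 4 lower. Gad2 was 2.27-fold higher, Kcnc2 2.01-fold higher, Gad1 and Crhbp had log2 ratios of 0.70 and a bound of 0.89, and Npy was 2.62-fold lower. The other members at least 2-fold lower, named after their values were seen, were Calb2 at 2.54-fold, Sst at 2.47-fold and Pvalb at 2.04-fold. The median was -1.03 at percentile 1.0 over 7 members without suffixed probe sets and -0.82 at percentile 0.88 over 7 members with the filter at percentile 75 of the mean level, and it lay below 0 in all 9 alternatives.

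**Figure D3:**
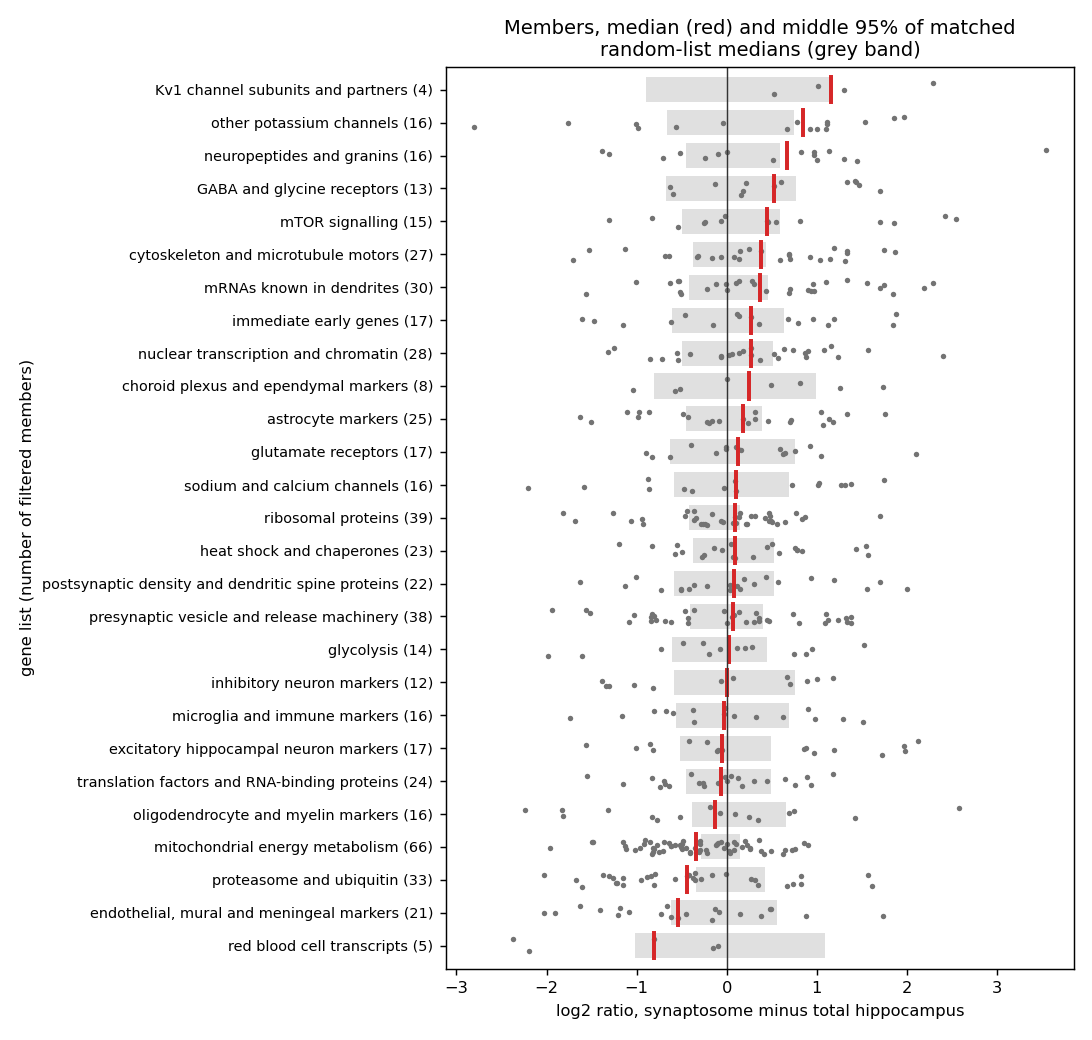
Log2 ratio of synaptosome over total hippocampus (horizontal axis) for the filtered members of the 27 gene lists (rows, with the number of members); each grey point is a gene, the red bar the list's median and the grey band the middle 95% of medians of 10000 matched random lists. The proteasome and mitochondrial medians, -0.44 and -0.34, lie left of their bands and those of other potassium channels and neuropeptides, 0.85 and 0.67, right of theirs.

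The control probe sets differed between the arrays. The β-actin control had a 3' to 5' signal ratio of 7.79 on the synaptosome array and 4.96 on the hippocampus array, while the GAPDH control had ratios of 1.07 and 1.05. The GAPDH signals were 43598 and 86466 at the 3' end, and the β-actin signals 40454 and 38944. The 9 bacterial hybridization controls had a median log2 ratio of -0.34 before centring, with a range from -1.14 to 0.64. The brightest controls, CreX, had the lowest ratios, but the ratios did not fall in step with brightness throughout. The BioB probe sets, with signals of 1624 to 3881, had -0.10 to 0.64 and BioC -0.07 and -0.52. BioDn had -0.42 and -0.34, and CreX, with signals of 67621 to 170950, -1.14 and -0.77. The BioC probe set at -0.52, with signals of 9224 and 13218, was dimmer than both BioDn probe sets.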

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

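The count of unnamed probe sets was added after the data were seen, and no test was run on it. Probe sets without a single gene symbol entered no gene count and no list, and signals in them differed between the arrays. Of 801 such probe sets past the filter, 139 were at least 2-fold higher in synaptosomes and 131 at least 2-fold lower. The highest above the floor on both arrays was rc_AA893870_at, with a log2 ratio of 3.15 and signals of 10061 and 1271. The lowest above the floor on both arrays was rc_AI007824_at, with a log2 ratio of -3.43 and signals of 42880 in synaptosomes and 519581 in the hippocampus, the brightest value on either array. No explanation was tested for them.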

How the results depend on the processing

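The floor at percentile 75, the restriction to genes above the floor on both arrays, and the use of one probe set per source sequence were chosen after the data were seen. The Kcna1 ratio lay between 2.11 and 3.56 in the 9 alternatives that could be run; 3.56 came from leaving out suffixed probe sets, which left only the probe set under the floor in the hippocampus. Genes at least 2-fold higher and lower, 522 and 391, numbered 214 and 147 with the filter at percentile 75 of the mean level, 173 and 136 with the floor at percentile 75 and 311 and 230 with genes above the floor on both arrays, each time with fewer genes counted. Without centring the mitochondrial median was -0.51. With the floor at percentile 75 the median of other potassium channels was -0.12 over 7 members and that of GABA and glycine receptors 0.073, and with the filter at percentile 75 of the mean level the presynaptic median was 0.35; beyond the loss of members, the cause was not tested. Of 238 list medians under the alternatives, 235 lay within the list's bootstrap interval. Of 1194 values of 153 named genes, 1126 lay within 1 SD between probe sets of the value given above, 63 lay farther off, and 5 of genes at least 2-fold higher or lower had the opposite sign, and 9 did with the other genes included. Several alternatives could not move a gene that far, so these counts say little about robustness. The centring shift was only -0.17, and a change of filter leaves the ratio of the brightest probe set as it was. For a gene with 1 probe set, the mean over probe sets changes nothing. With the mean over probe sets Kcnab2 was at -0.0367 and Kcnmb1 at -0.26, with the floor at percentile 75 Kcnmb1 was at -0.92 and Atf3 at 0.037, and without suffixed probe sets RT1-Ba was at -1.03. The SD between probe sets was 0.71 with the filter at percentile 75 of the mean level and 0.94 with one probe set per source sequence. The floor at percentile 10 was not run because it was negative. Signal over background limits the 241 and 319 genes above the floor on the synaptosome or hippocampus array alone, whose folds are bounds. No paired analysis was possible because each group had 1 array.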

Other observations

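The genes in the next paragraph and all tests of explanations in this part were chosen after the results were seen.

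Several genes were at least 2-fold higher in synaptosomes with every filtered probe set. Ppp1cb, a catalytic subunit of protein phosphatase 1, was 5.06-fold and at least 7.95-fold higher with its 2 probe sets. Ptk2b, a calcium-activated tyrosine kinase, was 3.95-fold and 2.86-fold higher, and Prkcb, a protein kinase C isoform, was higher with all 3 probe sets, by 2.01-fold to 3.60-fold. The amyloid precursor App was 2.77-fold and 2.36-fold higher, the vesicle protein Sv2b 2.56-fold and 2.35-fold, the RNA-binding protein Celf1 from 2.32-fold to 4.27-fold over 3 probe sets, and Kcnd2, an A-type potassium channel, 2.15-fold and at least 2.51-fold. Genes lower with every filtered probe set included Mog, 2.49-fold and at least 8.90-fold, Cd9, 3.26-fold and 2.06-fold, Resp18, 2.39-fold and 2.16-fold, Nedd8, a ubiquitin-like modifier, 2.60-fold and 2.19-fold, and the proteasome subunit Psmb2, 2.16-fold and 2.22-fold. The 2 probe sets of Ppp1cb, App, Cd9, Resp18 and Psmb2, and 2 of the 3 of Celf1, are designs on one source sequence, so their agreement is weaker support than that of independent sequences. The count of genes at least 2-fold lower with every probe set, 19, did not exceed the maximum of the shuffles, 19. For higher genes the count was 46, against a shuffle mean of 21.1 and maximum of 34. Agreement of probe sets is therefore weak support for any single gene named here.

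Of transcripts encoded in mitochondrial DNA, COX1 was 2.61-fold and 4.08-fold lower with 2 probe sets and COX3 2.41-fold lower, while COX2 was 1.52-fold higher. The hippocampus signals of COX1, 196646 and 263608, and of COX3, 158856, lay above the brightest synaptosome signal of any probe set, 96504. That of COX2, 61007, did not. Compression of bright signals on the synaptosome array was not tested for these transcripts and stays open.

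Genes of mitochondrial energy metabolism and of the proteasome had lower medians in synaptosomes. Compression of bright signals on the synaptosome array would lower ribosomal protein genes, which are at least as bright, by as much, but the mitochondrial median minus theirs was -0.43 (95% interval -0.70 to -0.07) and the proteasome median minus theirs -0.54 (-1.05 to -0.13). This argues against compression for the proteasome list, whose median was -0.62 at percentile 0.05 after loess correction. For the mitochondrial list compression stays open, since loess correction took its median from -0.34 to -0.18 and its percentile to 3.73. A further reason is that the brightest bacterial controls, CreX, were at -1.14 and -0.77 against -0.10 to 0.64 for the dimmest, BioB. These control ratios are before centring, unlike the list medians. Loss of short or degraded transcripts stays open: transcript lengths were not measured here, so the ribosomal protein median of 0.10 (-0.24 to 0.27) decides nothing, and the β-actin 3' to 5' ratio was 7.79 in synaptosomes and 4.96 in the hippocampus. That these mRNAs make up a smaller share of RNA at synapses may be stated only as a hypothesis, and a difference between the preparations stays open.

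Kcna1 was higher with both probe sets. Shuffling probe sets over 658 genes gave a mean of 0.34 and a maximum of 3 genes with all probe sets at or above 2.29, where 2 were observed, and over 429 genes with one probe set per source sequence a mean of 0.144 and a maximum of 2, where 1 was observed. The number of such genes did not exceed the maximum of the shuffles, and the study that made these arrays may have named Kcna1 because of them, so noise between probe sets stays open. A larger share of neuronal RNA would raise excitatory neuron markers by as much, and the upper bound of their median was 1.19. As a set these markers had a median of -0.05, or 0.41 after loess correction, below the lower Kcna1 ratio of 2.29. Yet 5 of 17 were at least 2-fold higher and 2 lower, and only excitatory cells were covered, so a larger neuronal share is not excluded. A difference between the preparations or their amplifications cannot be told apart from enrichment at synapses, which may be stated only as a hypothesis, because there was 1 array per group.

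Vascular markers had a median of -0.54, which lay inside the random lists at percentile 4.35 and was -0.13 at percentile 22.7 with genes above the floor on both arrays. A lower share of all non-neuronal cells would lower astrocyte markers alike; the vascular median minus the astrocyte median was -0.72 (95% interval -1.36 to 0.09), which includes 0, so this cannot be told apart. Loss of blood and vessel RNA during the preparation would lower red blood cell transcripts, and their percentile of 6.66 among random lists, with 5 members, leaves it open as well. No biological explanation was tested for this list.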
